A study of Mus musculus with 4 samples.

How the data were processed

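The study sorted retinal cells of BAC-Crx-EGFP mice at day E17.5 of embryonic development into an EGFP-positive and an EGFP-negative fraction and measured RNA from each fraction on Affymetrix whole-transcript arrays. A BAC-Crx-EGFP mouse carries a bacterial artificial chromosome, a long piece of genomic DNA, in which the enhanced green fluorescent protein is placed under the control of the photoreceptor gene Crx. Per the labels, total RNA of 100 ng per sample was extracted with TRIzol, amplified by a whole-transcript cDNA kit and labelled with biotin. The labels name 2 replicates per fraction, 4 arrays in all. They do not say whether the replicates came from separate animals, litters or sorts, so the p-values measure only the spread between these samples, which may be technical.

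The deposited values are normalised intensity values on a linear scale, 1 column per array. The submitters' processing notes name RMA, a method of background correction, quantile normalisation and probe summarisation for Affymetrix arrays, and the genome build mm8. The version of RMA, the probe sets summarised and any filter on them are not given in the sources used here. Values ran from 18.9 to 36625.2, and the 4 arrays had medians of 218.4 to 222.9. RMA usually gives log2 values, and the linear scale was inferred from this range. All values were above 0, and log2 was taken without a pseudocount. No column of values was left unused.

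The values cover 22431 features (probe sets). The platform annotation gave 1 gene symbol for 20176 of them, several for 412 and none for 1843. Features with several symbols or none stayed in the test and named no gene. The features with 1 symbol represent 18920 genes, of which 726 had more than 1 feature, and such a gene took the value of its feature with the highest mean over the 4 arrays. Symbols were compared through Entrez gene numbers with a RefSeq gene table of the assembly GRCm38.p6, and none needed updating. Because that assembly differs from mm8, and no genome was used here, no coordinates are given.

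Differences between the fractions were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend) on the log2 values of all 4 arrays. The direction is EGFP-positive minus EGFP-negative, and the replicate number did not enter the model. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all 22431 features, with a threshold of 0.05. Errors of log2 differences are limma's moderated standard errors (SE). The variance estimate had 5.27 degrees of freedom, 2 of them from the arrays and 3.27 from the prior. The number of arrays limits the precision. The median SE was 0.12 on the log2 scale, and the smallest difference called was 0.75 in size.

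The model, the rule for naming genes and 20 gene lists were fixed before the data were examined. The lists comprised photoreceptor transcription factors, cone and rod phototransduction, shared photoreceptor function, the photoreceptor ribbon synapse, the primary cilium, progenitors, the cell cycle, neurogenic precursors, 4 classes of other retinal neurons, glia, pigment cells, endothelium, microglia, erythroid cells, lens and the response to dissociation. Each list was tested against all other genes with camera, using its preset correlation between genes of 0.01 and 1 feature per gene, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the arrays, and fry, which asks whether the members of a list move on balance in 1 direction without comparing them with other genes, were run as alternatives. With an estimated correlation camera also judges its statistic by the 2 residual degrees of freedom of the arrays, which by itself raises the p-value. For each list, the number of members past the threshold is given over all features and adjusted over the list alone. List members for which the annotation used here held no feature of their own were not analysed here. They include Nr2e3, Pou4f2 and 7 of the 12 erythroid genes, most of them globins.

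The rule for genes named in the text had 3 parts. The first took the 12 genes with the largest positive and the 12 with the largest negative log2 difference among features with 1 symbol that passed the threshold and whose fractions did not overlap. The second always took Crx, Otx2, Neurod1, Prdm1, Nrl, Nr2e3, Thrb, Rxrg, Opn1sw, Opn1mw, Arr3 and Pax6, and some further genes that are not reported here. The third took up to 4 called members of each list with the largest difference, or the 2 largest where no member was called. A gene outside the rule is given as chosen after its values were seen.

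The pipeline was tested on simulated data with the 22431 real feature means, 2 arrays per fraction, independent noise and 200 changed features. Over 10 simulations it recovered 56.0% of features changed 2-fold, 95.1% of those changed 4-fold and 98.8% of those changed 8-fold. Of a mean of 175.5 features called, 9.1 were false, or 5.2%. Camera called 2 of 190 unshifted lists and the shifted list in 10 of 10 simulations. The simulated noise was independent between genes, whereas the correlation estimated in the data was 0.848 for the cell cycle list. These rates therefore need not hold for the real data.

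The alternatives tried were a block for the replicate number, another quantile normalisation, centring of each array on its median, removal of features below the 25th or 50th percentile of mean intensity, eBayes with a trend and with a robust trend, other thresholds, 1 feature per gene or the mean of its features, and each array left out in turn.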

Results

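Gene expression was measured in cells sorted from the retina of BAC-Crx-EGFP mice at day E17.5 of embryonic development, as 2 EGFP-positive and 2 EGFP-negative samples on 1 array each. Crx encodes a homeodomain transcription factor of photoreceptors and their precursors, and the reporter marks cells in which its regulatory sequences are active. The comparison asks how the expression profile of the EGFP-positive cells differs from that of the EGFP-negative cells. Across the 22431 features, Spearman's correlation was 0.985 between the positive arrays and 0.987 between the negative arrays. Across fractions it ranged from 0.954, between positive replicate 2 and negative replicate 1, to 0.980, between positive replicate 1 and negative replicate 2.

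EGFP-positive cells had higher expression of photoreceptor genes, and EGFP-negative cells of the progenitor gene Sox2. Rbp3, which encodes the retinoid-binding protein of the space around photoreceptors, was 20.7-fold higher in the positive fraction (log2 difference 4.37 ± 0.19, SE, n = 2 per fraction, limma adjusted p = 0.00576). Crx itself was 12.6-fold higher (3.66 ± 0.19, adjusted p = 0.00596). Sox2 fell by 1.36 ± 0.10 on the log2 scale (adjusted p = 0.0119). Of 22431 features, 184 were higher and 32 lower in the positive fraction at an adjusted p under 0.05, and 145 and 18 of these by at least 2-fold. All 216 separated the positive from the negative arrays without overlap, as did 47.6% of all features against 33.3% by chance.

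These counts varied with the arrays used. Without positive replicate 1, limma called 667 features higher and 762 lower, and without positive replicate 2 it called 147 and 12. Without either negative array it called 0 in both directions, with 2346 (without negative replicate 1) and 3134 (without negative replicate 2) features at an unadjusted p under 0.05 against 4298 with all 4 arrays. The 216 features kept their direction in each of these fits. Because their fractions do not overlap, leaving out 1 array could not turn it, so this is no sign of stability.

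Among called genes, those with the largest differences toward the positive fraction were mostly known from photoreceptors. After Rbp3 they were Impg2, a proteoglycan of the matrix around photoreceptors (log2 difference 4.22 ± 0.23, adjusted p = 0.00655), and Cngb3, a subunit of the cone cyclic nucleotide-gated channel (4.08 ± 0.42, adjusted p = 0.0293). Crx was followed by Cdhr1, a cadherin of photoreceptor outer segments (3.64 ± 0.27), and Mak, a kinase of the photoreceptor cilium (3.49 ± 0.20). Egflam, which encodes the synaptic matrix protein pikachurin, was higher by 3.46 ± 0.11, and Doc2b, a calcium sensor of vesicle release, by 3.21 ± 0.23. Angpt1, a ligand of the endothelial receptor Tek, was higher by 3.14 ± 0.36. The group was completed by Rpgrip1, a protein of the connecting cilium (3.06 ± 0.23), the photoreceptor phosphatase Ppef2 (3.02 ± 0.16) and the membrane protein Slitrk6 (3.01 ± 0.23). Adjusted p for these genes ranged from 0.00576 for Rbp3 and Egflam to 0.0389 for Angpt1.

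Transcription factors of the photoreceptor lineage were higher in the positive fraction. The feature for Crx (10560168, Entrez gene 12951) read 3628.7 and 4758.8 in the positive replicates and 292.2 and 370.1 in the negative ones, or 12.02 ± 0.28 against 8.36 ± 0.24 as log2 intensity (SD, n = 2). Crx drives the reporter by which the cells were sorted, and the labels do not state whether the transgene adds to this reading. Prdm1, which favours photoreceptor over bipolar fate, was higher by 2.61 ± 0.18 on the log2 scale (adjusted p = 0.0111). Neurod1, a factor of photoreceptor differentiation, was higher by 2.06 ± 0.14 (adjusted p = 0.0111), and Otx2, which acts upstream of Crx, by 1.94 ± 0.11 (adjusted p = 0.00655). Of the 13 measured members of this list 5 were called, the fifth being Mef2d (1.79 ± 0.18, adjusted p = 0.0290), chosen after its values were seen. Adjusted over the list alone 8 were called, and 12 of 13 had a positive difference, with a median of 1.58. The camera test of the list gave an adjusted p of 4.74e-10, and adjusted p = 0.272 with an estimated correlation.

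Thrb, Rxrg and Nrl, tied to cone or rod identity, varied more between the positive replicates than the called factors. Their SD of log2 intensity was 1.27, 0.46 and 0.49, against at most 0.35 for the called factors, and a low spread itself favours a call. The other members of the list that were not called varied less there than Crx. Thrb, whose product directs the cone opsin pattern, had intensities of 785.9 and 2722.1 in the positive and 155.0 and 178.2 in the negative fraction (log2 difference 3.14 ± 0.56, adjusted p = 0.0826). Rxrg, a nuclear receptor of cones, differed by 1.58 ± 0.24 (adjusted p = 0.0634). Nrl, which specifies rods, differed by 0.42 ± 0.25 (adjusted p = 0.462), with a 95% interval from -0.22 to 1.06. Without positive replicate 1 the log2 difference was 4.03 for Thrb and 1.91 for Rxrg. Without positive replicate 2 it was 2.24 for Thrb and 1.26 for Rxrg. With all arrays and a robust variance trend in limma the adjusted p was 0.0474 for Rxrg.

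Cone phototransduction genes were higher in the positive fraction, with 6 of 13 members called over all features and 8 adjusted over the list alone. Cngb3 led the list, followed by Pde6c, the catalytic subunit of the cone phosphodiesterase (log2 difference 2.97 ± 0.31, adjusted p = 0.0306). The cone transducin subunit genes Gnb3 and Gnat2 differed by 2.86 ± 0.13 (adjusted p = 0.00576) and 2.82 ± 0.29 (adjusted p = 0.0293). The median over the list was 1.83, camera gave an adjusted p of 8.17e-10, and the list had adjusted p = 0.149 with an estimated correlation. The short-wavelength opsin gene Opn1sw read 671.0 and 262.5 in the positive and 111.5 and 124.5 in the negative fraction (1.83 ± 0.43, adjusted p = 0.116). Its log2 difference was 1.16 without positive replicate 1 and 2.51 without positive replicate 2. The medium-wavelength opsin gene Opn1mw read 102.6 to 112.4 on the 4 arrays (-0.01 ± 0.11, adjusted p = 0.983), a difference that turned to 0.015 when each array was centred on its median and also turned positive without positive replicate 1 or negative replicate 1. The cone arrestin gene Arr3 differed by 0.23 ± 0.12 (adjusted p = 0.406).

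Rod phototransduction genes differed less, with none of 11 members called by limma over all features, 2 higher adjusted over the list alone and 3 higher at an unadjusted p under 0.05. The largest differences were 0.87 ± 0.20 for Sag, the rod arrestin gene (adjusted p = 0.112), and 0.61 ± 0.18 for Reep6, which acts in rod membrane trafficking (adjusted p = 0.162). Without positive replicate 1 Reep6 differed by 0.85. The list had a median of 0.29, and 4 of its members lay below the lower quartile of mean intensity. Camera gave an adjusted p of 0.0251, and the list had adjusted p = 0.391 with an estimated correlation. The adjusted p was also 0.0508 without positive replicate 1, 0.0511 without negative replicate 2 and 0.0688 after removal of features below the 25th percentile. The difference between the cone and the rod list was not tested.

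**Figure D1:**
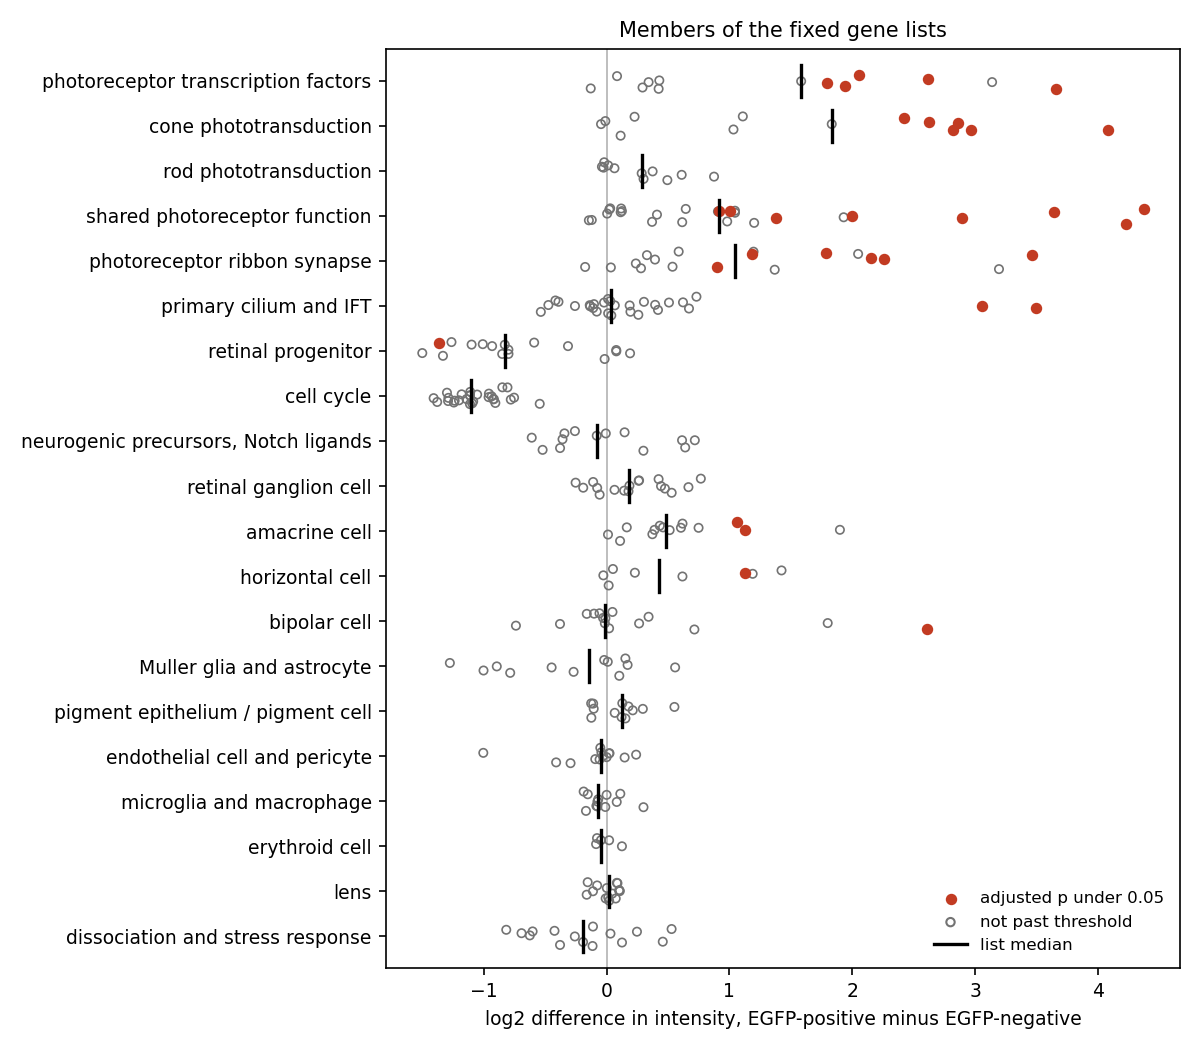
Each point is 1 gene of a list fixed before the data were examined, placed by its log2 difference in intensity between the EGFP-positive and EGFP-negative fractions (x axis). Lists are on the y axis, red points passed an adjusted p under 0.05, open points did not, and black bars are list medians, from 1.83 for cone phototransduction to -1.10 for the cell cycle.

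Genes shared by rods and cones were higher in the positive fraction. Of 26 measured members, 8 were called over all features, 17 were called adjusted over the list alone, and 24 had a positive difference. Beside Rbp3, Impg2 and Cdhr1, the largest difference was that of the transducin-binding gene Pdc (log2 difference 2.89 ± 0.13, adjusted p = 0.00576). The list had a median of 0.91 and a camera adjusted p of 1.34e-13, with adjusted p = 0.149 with an estimated correlation.

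Genes of the photoreceptor ribbon synapse, where vesicles are released continuously, were higher as well. Of 18 members, 6 were called over all features, 15 were called adjusted over the list alone, and 17 had a positive difference. After Egflam the leading called members were the synaptic vesicle genes Sv2b (log2 difference 2.25 ± 0.12, adjusted p = 0.00596) and Syp (2.15 ± 0.16, adjusted p = 0.0133). Dmd, chosen after its values were seen, differed by 3.19 ± 0.46 and was not called (limma adjusted p = 0.0601). Cacna2d4, an auxiliary subunit of the presynaptic calcium channel, differed by 1.79 ± 0.10 (adjusted p = 0.00690). The list had a median of 1.04 and a camera adjusted p of 9.35e-14, with adjusted p = 0.149 with an estimated correlation.

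In the list of genes of the primary cilium and intraflagellar transport, Mak and Rpgrip1 were higher and 26 of 28 members were not called. Adjusted over the list alone, 4 were higher and 1 was lower. The median was 0.03, the mean 0.30 and the camera adjusted p 0.0896. It was 0.0315 without negative replicate 1 and 0.0199 without positive replicate 2.

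The next 12 genes had the largest differences toward the negative fraction among called genes. Aldh1a3, an enzyme of retinoic acid synthesis, fell by 1.63 ± 0.21 on the log2 scale in the positive fraction (adjusted p = 0.0457). The cytoskeletal and signalling protein gene Ajuba fell by 1.48 ± 0.18 and the DNA repair gene Fignl1 by 1.47 ± 0.13. Rfc4, part of the clamp loader at the replication fork, had a difference of -1.47 ± 0.17, Dscc1, of sister chromatid cohesion, of -1.37 ± 0.13 and Gins1, of the replicative helicase, of -1.33 ± 0.16. Oip5, needed to build centromeres, fell by 1.19 ± 0.12. The others were Sox2, the protease gene Prss23 (-1.23 ± 0.15), the chloride channel gene Ano1 (-1.18 ± 0.14), Dbi, which encodes an acyl-CoA binding protein (-1.17 ± 0.11), and the kinase gene Vrk2 (-1.14 ± 0.13). Adjusted p ranged from 0.0119 for Sox2 to 0.0457 for Aldh1a3. Without positive replicate 2 the adjusted p was 0.0649 for Rfc4, 0.0508 for Prss23, 0.0561 for Oip5, 0.0684 for Ano1 and 0.0632 for Vrk2, and Prss23 had 0.0509 after another quantile normalisation.

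Retinal progenitor genes were lower in the positive fraction as a list, with a median log2 difference of -0.83 over 17 members and 14 members below 0. Sox2 alone was called over all features, 11 members were called lower adjusted over the list alone, and 11 were lower at an unadjusted p under 0.05. Pax6, which progenitors share with amacrine, horizontal and ganglion cells, differed by 0.19 ± 0.11 (adjusted p = 0.432). The camera adjusted p was 1.22e-05, and the list had adjusted p = 0.455 with an estimated correlation and 0.123 by fry. The list's median difference from negative replicates 1 and 2 was -0.59 and -0.53 for positive replicate 1 and -1.27 and -1.07 for positive replicate 2, and 12 of 17 members were lower in replicate 2 than in replicate 1 of both fractions.

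All 28 measured cell cycle genes had a lower mean in the positive fraction, with a median log2 difference of -1.10, or 2.15-fold higher expression in the negative cells. None was called by limma over all features, 19 were called adjusted over the list alone, and 23 had an unadjusted p under 0.05. The largest differences were those of the spindle checkpoint kinase gene Bub1 (-1.41 ± 0.35, adjusted p = 0.125) and of Pcna, the sliding clamp of DNA polymerase (-1.38 ± 0.25, adjusted p = 0.0836), whose 2 features differed by -1.44 and -1.38. Without positive replicate 1 the difference was -1.91 for Bub1 and -1.72 for Pcna. The camera adjusted p of the list was 5.86e-13, and the list had adjusted p = 0.455 with an estimated correlation and 0.247 by fry. The list's median difference from negative replicates 1 and 2 was -0.77 and -0.44 for positive replicate 1 and -1.71 and -1.37 for positive replicate 2.

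**Figure D2:**
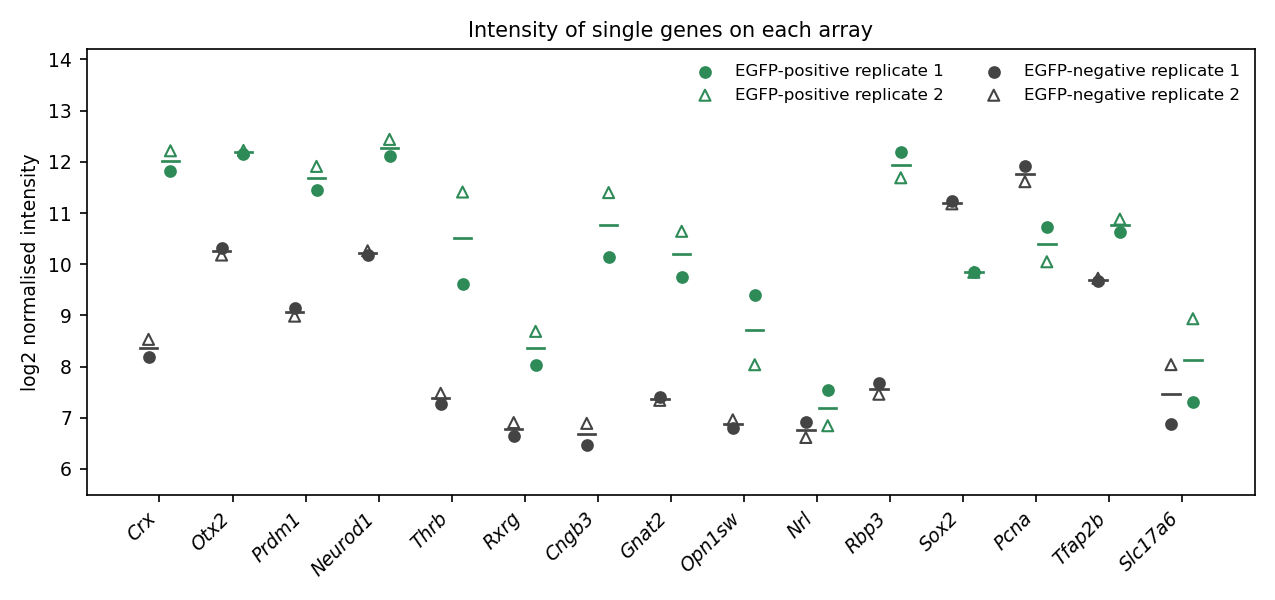
Log2 normalised intensity (y axis) of 15 named genes on each of the 4 arrays, green for the EGFP-positive and dark grey for the EGFP-negative fraction, with circles for replicate 1, triangles for replicate 2 and horizontal bars for the mean of each fraction. Crx is at 12.02 against 8.36 as the mean of the fractions, and Thrb, Opn1sw and Pcna show replicates of the positive fraction that lie apart.

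Genes of neurogenic precursors and Notch ligands had 5 members above 0 and 8 below. None of the 13 was called by limma over all features, 3 were higher adjusted over the list alone, and 3 had an unadjusted p under 0.05. The Notch ligand gene Dll3 differed by 0.72 ± 0.10 (adjusted p = 0.0516) and the antiproliferative gene Btg2 by 0.64 ± 0.15 (adjusted p = 0.121). The adjusted p of Dll3 was 0.0469 with each array centred on its median. It was 0.0421 in a limma fit over the 18920 genes, each as the mean of its features. The log2 difference of Dll3 was 0.72 there too, so only the fit and the adjustment changed. Without positive replicate 1 Dll3 differed by 0.71. The median of the list was -0.08 and the mean -0.01, while camera gave the direction as higher (adjusted p = 0.461). Without positive replicate 2 the list had an adjusted p of 0.0287, and without positive replicate 1 its direction turned (adjusted p = 0.435).

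Among other retinal neurons, amacrine cell genes were higher in the positive fraction, with all 14 measured members above 0 and a median log2 difference of 0.49. The transcription factor genes Tfap2a (1.12 ± 0.14, adjusted p = 0.0429) and Tfap2b (1.06 ± 0.12, adjusted p = 0.0399) were called over all features, and 9 members were called adjusted over the list alone. The camera adjusted p was 8.91e-08, and the list had adjusted p = 0.149 with an estimated correlation. Without positive replicate 2 the adjusted p was 0.0625 for Tfap2a and 0.0647 for Tfap2b, and with eBayes with a trend it was 0.0516 for Tfap2b. Of 8 horizontal cell genes, 7 had a positive difference, with a median of 0.42. Tfap2a, which stands in both lists, was the 1 member called, over all features and adjusted over the list alone (camera adjusted p = 0.0149). The horizontal cell list had adjusted p = 0.455 with an estimated correlation and 0.197 by fry. Its median difference from negative replicates 1 and 2 was 0.22 and 0.24 for positive replicate 1 and 0.70 and 0.68 for positive replicate 2.

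Of 15 bipolar cell genes, Neurod4 was called, a proneural transcription factor gene also expressed in other retinal precursors (log2 difference 2.60 ± 0.10, adjusted p = 0.00576). Adjusted over the list alone, 3 members were called higher. The list had a median of -0.01, a mean of 0.29 and a camera adjusted p of 0.180, with fry giving 0.0355.

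None of 17 retinal ganglion cell genes was called by limma over all features or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The differences were 0.77 ± 0.18 for the neuronal tubulin gene Tubb3 (adjusted p = 0.112) and 0.67 ± 0.62 for the glutamate transporter gene Slc17a6 (adjusted p = 0.670), which turned to -0.14 without positive replicate 2. The list's median was 0.19 and its camera adjusted p 0.278, or adjusted p = 0.872 with an estimated correlation. These genes differed between replicates, with a median log2 difference of replicate 2 minus replicate 1 of 0.74 in the positive and 1.14 in the negative fraction, and 14 of 17 were higher in replicate 2 of both. Without negative replicate 2 the list was higher in the positive fraction (adjusted p = 4.44e-05), as it was without positive replicate 1 (adjusted p = 0.00730). Both calls rest on the preset correlation of 0.01, while the correlation estimated over the 4 arrays was 0.584. Without negative replicate 1 (adjusted p = 0.119) or positive replicate 2 (adjusted p = 0.689) its direction turned.

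Glial and non-neural lists held no called member, over all features or adjusted over the list alone. For Müller glia and astrocytes the median of 12 genes was -0.14 (camera adjusted p = 0.344), with 3 lower at an unadjusted p under 0.05 in limma, and its largest differences were those of the glutamate transporter gene Slc1a3 (-1.27 ± 0.34, adjusted p = 0.143) and the carbonic anhydrase gene Car2 (-1.001 ± 0.49, adjusted p = 0.357). Slc1a3 differed by -1.79 without positive replicate 1. For the pigment epithelium the median of 12 genes was 0.13 (adjusted p = 0.188), with 2 higher at an unadjusted p under 0.05. Rgr, an opsin of the pigment epithelium, differed by 0.55 ± 0.17 (adjusted p = 0.174) and the pigment gene Tyrp1 by 0.30 ± 0.11 (adjusted p = 0.252). Without positive replicate 1 Rgr differed by 0.77. For endothelium and pericytes the median of 13 genes was -0.04 (adjusted p = 0.552), with 1 lower at an unadjusted p under 0.05. Kdr, a receptor of vascular growth factor that retinal progenitors also express, differed by -1.003 ± 0.53 (adjusted p = 0.403), and the collagen gene Col4a1 by -0.41 ± 0.12 (adjusted p = 0.152). Without positive replicate 1 Kdr differed by -1.76.

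For microglia the median of 12 genes was -0.07 (camera adjusted p = 0.824), with 1 higher at an unadjusted p under 0.05 in limma. The complement gene C1qa differed by 0.30 ± 0.12 (adjusted p = 0.256) and the receptor gene Csf1r by -0.19 ± 0.12 (adjusted p = 0.509). For 5 erythroid genes the median was -0.05 (adjusted p = 0.875), with 0 at an unadjusted p under 0.05, a difference of 0.13 ± 0.16 for the haem synthesis gene Alas2 (adjusted p = 0.779) and one of -0.09 ± 0.12 for the anion exchanger gene Slc4a1 (adjusted p = 0.802). For 15 lens genes the median was 0.02 (adjusted p = 0.849), with 0 at an unadjusted p under 0.05, a difference of -0.16 ± 0.10 for the crystallin gene Crybb3 (adjusted p = 0.473) and one of -0.15 ± 0.10 for the lens channel gene Mip (adjusted p = 0.510). Low intensity may have limited these lists, with 6 pigment, 5 microglial and 4 lens genes below the lower quartile of mean intensity. The direction of the microglial, erythroid and lens lists turned when single arrays were left out, with adjusted p of 0.960, 0.926 and 0.922 without negative replicate 1. It also turned without positive replicate 1 for microglia (adjusted p = 0.924) and without positive replicate 2 for erythroid (adjusted p = 0.817) and lens genes (adjusted p = 0.967).

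Of 15 genes of the response to dissociation and stress none was called over all features or adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05 in limma. The median was -0.19 (camera adjusted p = 0.875), and its direction turned without negative replicate 1 (adjusted p = 0.347) and without positive replicate 2 (adjusted p = 0.341). The immediate early genes Fos and Egr2 differed by -0.82 ± 0.47 (adjusted p = 0.441) and -0.69 ± 0.57 (adjusted p = 0.615). Fos read 952.8 and 442.3 in the positive and 1610.1 and 811.3 in the negative replicates 1 and 2. Within fractions, the list's median of replicate 2 minus replicate 1 was -0.48 in the positive and -0.62 in the negative fraction, and 10 of 15 members were lower in replicate 2 of both. Cell cycle genes had medians of -0.89 and -0.38 in the same comparison, with 26 of 28 members lower in both.

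**Figure D3:**
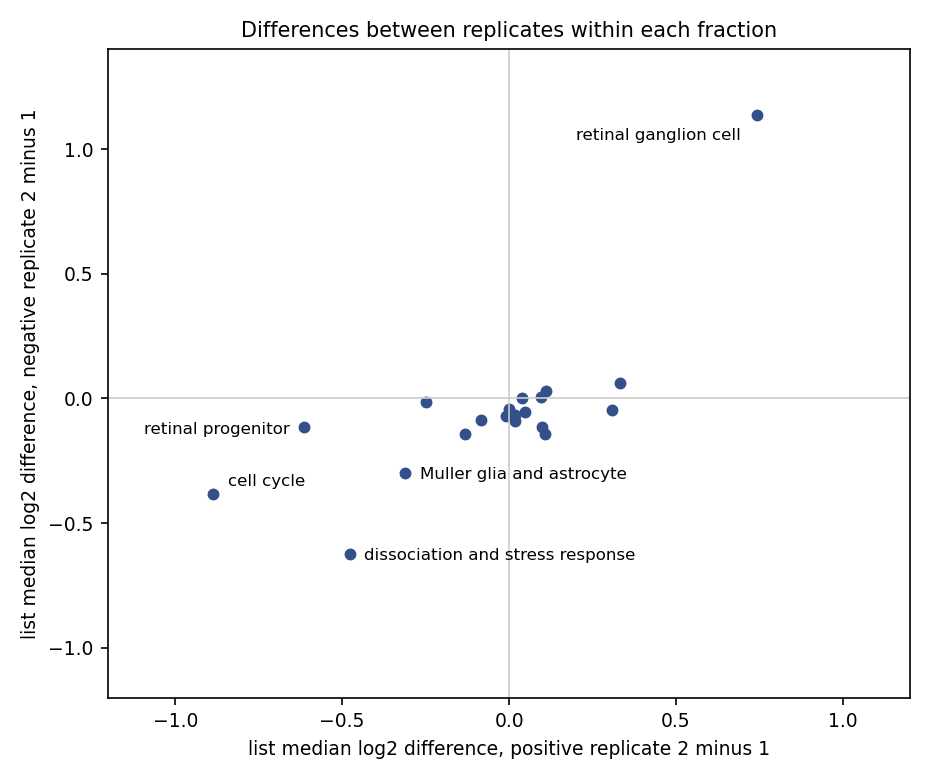
Each point is 1 of the 20 gene lists, placed by its median log2 difference of replicate 2 minus replicate 1 within the EGFP-positive (x axis) and EGFP-negative fraction (y axis). Retinal ganglion cell genes lie at 0.74 and 1.14, and cell cycle genes at -0.89 and -0.38.

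In a principal component analysis of the log2 values, the first component held 71.4% of the variance and placed the positive arrays at -12.4 (replicate 1) and -39.8 (replicate 2) and the negative arrays at 33.3 and 18.9. The second component, with 19.8%, placed both replicates 1 above 0 (18.5 and 9.23) and both replicates 2 below 0 (-7.58 and -20.1).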

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

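The alternatives were planned, and the correlation of same-numbered arrays was computed with the results at hand. The 216 features called kept their direction in every fit. Because their fractions do not overlap, this was fixed in advance for the replicate block and for fits with 1 array left out. Of those measured, 209 were still called after another quantile normalisation and 216 with each array centred on its median. Without features below the 25th and 50th percentile 208 of 213 and 188 of 189 were called, with a variance trend 178 and with a robust trend 204. Features called higher numbered 29 at an adjusted p under 0.01 and 635 under 0.1, and those called lower 0 and 453, against 184 and 32. Lower features numbered 18 with a fold of at least 2, 18 with that fold in all 4 array pairs and no test, 21 with a variance trend and 52 with 1 feature per gene tested. With 1 array left out, higher features ranged from 0 to 667 and lower features from 0 to 762. The lone array of a fraction is then assumed to vary like the pair, so the spread comes from the other fraction, and the positive arrays differ more (SD of log2 differences 0.285) than the negative ones (0.253). With only the positive arrays to give the spread, 0 features were called, with 2346 and 3134 at an unadjusted p under 0.05 in limma. All 37 named genes that had been called lost their call in those fits, 7 lost it without positive replicate 2, 1 with a variance trend and 1 with another quantile normalisation. The replicate numbers are shared by the fractions, but the labels do not say whether they mark a shared animal or day, so the samples were not treated as paired, and whether they are remains open. Deviations of same-numbered arrays correlated with an r of 0.482 across features. With the replicate number as a block, 1377 features were higher and 1500 lower, all 216 were kept, and the ganglion cell list had an adjusted p of 0.0154. The block also brought a call to 15 named genes that had none, among them Bub1 (adjusted p = 0.00895), Pcna (0.00544), Thrb (0.00846), Rxrg (0.00404), Opn1sw (0.0229) and Dll3 (0.0122). The immediate early genes Fos (0.01009) and Egr2 (0.01465), lower in the positive fraction, were also among them. With an estimated correlation the 9 lists called lost their call, with adjusted p of 0.149 for the amacrine, cone, ribbon synapse and shared photoreceptor lists, 0.272 for photoreceptor transcription factors, 0.391 for the rod list and 0.455 for the cell cycle, horizontal cell and progenitor lists. The estimated correlation was 0.848 for cell cycle and 0.584 for ganglion cell genes. It was -0.040 for the cone, -0.040 for the amacrine, -0.048 for the rod and 0.010 for the shared photoreceptor list, near or below the preset 0.01. A higher correlation between genes therefore does not account for the lost calls of these lists. In this setting camera judges its statistic by the 2 residual degrees of freedom of the arrays. For the cone list the unadjusted camera p was 2.04e-10 with the preset correlation and 0.0214 with the estimated one. With fry the adjusted p was 0.247 for the cell cycle, 0.197 for the horizontal and 0.123 for the progenitor list, and 0.0355 for the bipolar list. Without features below the 25th percentile the rod list had an adjusted p of 0.0688 and the microglial list turned direction at 0.878. For ranges with 1 array left out, adjusted p ran from 0.00272 to 0.0511 for the rod list, 0.0199 to 0.152 for the cilium list, 0.0287 to 0.698 for neurogenic precursors and 4.44e-05 to 0.689 for ganglion cells, the last 2 with turns in direction. Lists that were not called and turned direction had 0.151 to 0.347 for stress, 0.7002 to 0.926 for erythroid, 0.531 to 0.967 for lens and 0.531 to 0.960 for microglial genes. Among genes that were not called, the log2 difference of Opn1mw was 0.015 with each array centred on its median and -0.076 to 0.056 with 1 array left out, while Alas2 ranged from -0.068 to 0.32, Slc17a6 from -0.14 to 1.48 and Slc4a1 from -0.19 to 0.024. Beyond the degrees of freedom of camera, the smaller number of arrays or genes, and the assumed correlation for lists with a higher estimate, the cause was not tested. Low intensity may limit the rod, bipolar, pigment, microglial, erythroid and lens lists. With 2 arrays per fraction simulated 2-fold changes were recovered in 56.0% of cases.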

Other observations

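All tests in this part, and the 5 gene groups described first, were chosen only after the results had been seen. Beyond the fixed lists, genes of the DNA replication machinery were lower in the positive fraction, with all 34 measured members below 0 and a median log2 difference of -0.90. Over all features 4 were called by limma, namely Gins1, Rfc4 and Dscc1 and the checkpoint kinase gene Chek1 (-1.06 ± 0.11, adjusted p = 0.0293). The primase gene Prim1 differed by -1.64 ± 0.27 (adjusted p = 0.0751). Camera gave an adjusted p of 6.40e-24 over the 5 groups, with adjusted p = 0.156 with an estimated correlation. Of 10 genes of retinoic acid synthesis, binding and breakdown, 8 were below 0 and Aldh1a3 was called, while the degrading enzyme gene Cyp26a1 differed by -1.75 ± 0.45 (adjusted p = 0.135). That group had a median of -0.30, a camera adjusted p of 0.00579 and adjusted p = 0.172 with an estimated correlation. Of 14 peroxiredoxin, thioredoxin and related genes, which keep the cell's redox balance, 12 were below 0 with a median of -0.33. Prdx1 (-1.05 ± 0.12, adjusted p = 0.0399) and Txn1 (-1.01 ± 0.10, adjusted p = 0.0272) were called lower, camera gave 1.72e-05, and the group had adjusted p = 0.156 with an estimated correlation.

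Genes of regulated exocytosis outside the ribbon synapse list were higher in the positive fraction, with 24 of 26 above 0 and a median of 0.50. Besides Doc2b, the granin genes Chgb (2.03 ± 0.23, adjusted p = 0.0374) and Chga (0.86 ± 0.11, adjusted p = 0.0495) were called by limma, and the vesicle fusion gene Snap25 differed by 2.32 ± 0.31 (adjusted p = 0.0506). Camera gave 2.66e-10 for this group, with adjusted p = 0.156 with an estimated correlation. Of 17 genes of jumonji histone demethylases, 15 were above 0 with a median of 0.31. Kdm5b (1.22 ± 0.10, adjusted p = 0.0151), Kdm7a (1.11 ± 0.13, adjusted p = 0.0416) and Kdm6b (0.96 ± 0.10, adjusted p = 0.0290) were called higher. Camera gave 2.63e-07, with adjusted p = 0.156 with an estimated correlation. These groups were formed from genes that had already been seen to differ, so their tests are not independent evidence of direction.

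Of the 3 ways to split the 4 arrays into pairs, 1 gave as many called features as the real split, namely the real split itself with 216, and the highest of the others gave 0. With 3 splits no share under 0.05 can be reached. At an unadjusted p under 0.05, limma gave 4298 features for the real split, 816 for the split by replicate number and 95 for the crossed one. In the other splits each pair holds an array of either fraction, so the fraction difference adds to their residual spread and lowers their counts. They are therefore no reference for chance.

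Ganglion cell genes differed between replicate numbers in both fractions, by a median of 0.74 (quartiles 0.43 to 1.21) in the positive and 1.14 (0.67 to 1.36) in the negative fraction on the log2 scale. Scaling of the arrays would move genes of like intensity alike. The 100 genes nearest in mean intensity to each ganglion cell gene had a median of -0.0306 (quartiles -0.15 to 0.11) in the negative fraction. In the positive fraction it was -0.0057 (-0.16 to 0.14). Quantile normalisation, a step of RMA, brings such medians near 0 by design. They show only that no shift by intensity was left in these values to account for the whole difference. A preparation shared by the arrays of a number stays open as a hypothesis, and the correlation of replicate 2 minus replicate 1 between fractions, r = 0.482 across features, which are not independent, is consistent with it (Spearman's rho 0.401, and r = 0.472 without list members). A difference in developmental stage between the samples of a number, all given the same age in the labels, was not tested and stays open.

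Cell cycle genes were lower in the positive fraction without a single call, and their level in positive replicate 1 lay between that of positive replicate 2 and those of the negative arrays. Cells of the negative fraction in positive replicate 1 are a candidate explanation. Relative to positive replicate 2, cell cycle genes would need 44.1% of negative-fraction RNA (quartiles 37.0 to 58.6), and 36 photoreceptor genes with a log2 difference of at least 1 gave a median of 28.4% with overlapping quartiles (-12.2 to 49.99). Of these, 25 were lower in positive replicate 1 than in replicate 2, while others, such as Rbp3, Opn1sw, Gngt2, Rp1, Pdc, Unc119 and Ccdc136, were higher there. The photoreceptor quartiles take in both no admixture and the median share of the cell cycle genes, so they cannot decide. Of 28 cell cycle genes, 26 were lower in replicate 2 of both fractions (median -0.38 in the negative one). Sox2 read 921.5 and 917.5 in positive replicates 1 and 2, while the progenitor list had a median of -0.61 for replicate 2 minus 1. A difference in the stage of the sorted cells between replicates was not tested and stays open.

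Amacrine cell genes were higher in the positive fraction, with log2 differences from 0.01 ± 0.12 for Chat to 1.90 ± 0.41 for Meis2. If a lower share of dividing cells raised all other types alike, ganglion cell genes should be as high, and the amacrine median exceeded theirs in 3 of 4 array pairs, with differences from -0.68 to 1.37 over the 4 pairs. The pair that went the other way was positive replicate 2 minus negative replicate 1, with medians of 0.52 for amacrine and 1.195 for ganglion cell genes. Between arrays of the same number they were 0.55 and 0.30 for replicate 1, and 0.55 and 0.07 for replicate 2. The replicate difference of the ganglion cell genes keeps this explanation open. More amacrine cells among those sorted, and expression of these genes in photoreceptor precursors themselves, were not tested and stay open.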
